A study of Mus musculus with 6 samples.

How the data were processed

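Total RNA of whole mouse testis was extracted with Trizol and made into Illumina TruSeq small RNA libraries of the 18 to 35 nt fraction, per the labels' protocols. Animals of a genotype were pooled before sequencing, 7 or 8 per pool at 16.5 dpc and 3 at 10 dpp, per the series' design text. The 6 libraries were Dnmt3L WT and KO at 16.5 dpc, Dnmt3L WT and KO at 10 dpp, and Miwi2 WT and KO at 10 dpp, with littermates as WT. Each deposited file lists a read sequence and the count of reads with exactly that sequence, and the unit of all values is the raw count. The deposited counts had no header, were whole numbers, and covered reads of any length up to 50 nt, or 100 nt in the Dnmt3L libraries of 10 dpp. The only genome build in the submitters' processing notes is mm9. The trimming, aligner and filters are not given in the sources used here.

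Library totals were 42370622, 47232494, 38069968, 28701563, 45010155 and 37218684 reads in the order given above, with 966003 to 6478621 distinct sequences. A share of 85.2% to 95.6% of reads had 18 to 35 nt, and 0.313% to 0.399% of reads still held the first 12 bases of the TruSeq 3′ adapter. A library's depth sets a floor of 3 counts, or 0.0635 to 0.105 RPM. Intervals are 95% exact Clopper-Pearson, Poisson or conditional binomial intervals. They cover counting error only, since PCR reads carry no molecular identifiers, and no spread between animals can be estimated from 1 pool per group.

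The references at hand were the GENCODE vM21 transcripts and annotation of GRCm38, without a genome sequence or a repeat annotation. Printed coordinates are therefore on GRCm38 and not on mm9. Fixed genomic windows and repeat families, planned before the data were examined, were replaced by transcripts and by transposon segments found inside transcripts. Reads of 18 to 32 nt were matched without mismatches, on both strands, to the longest transcript of each of 55450 genes. A read was assigned to the first class that applied: miRNA gene, other small RNA, repeat-like (found in at least 10 genes other than pseudogenes, both orientations together), sense to a transcript, antisense to a transcript, or unmatched. A read found in several genes was divided evenly over them. Of the reads of piRNA size (24 to 32 nt), 35.7% to 56.1% matched a transcript, so intergenic piRNA clusters and most transposon copies were not analysed here. Levels are reads scaled to 1e6 reads of the library (RPM), and for miRNAs to 1e6 miRNA reads (12058824 to 24282734 per library).

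Transposon segments were located with 10 pairs of PCR primers for L1 and endogenous retroviruses. The primers come from general knowledge of the field and were chosen after the files were first read, and the family names rest on them. Exact matches and matches with 1, 2 or 3 mismatches were looked at, as was assembly of overlapping reads, before up to 2 mismatches per primer were settled on. A pair had to lie within 600 nt in a transcript, with a spacing within 3 nt of its most frequent one, and a flank of 300 nt was added on each side. A read belonged to a segment if it lay in the windows of at least 2 genes or inside the primer-bounded part. The pairs were found in 14 genes for the L1 Tf 5′ UTR, 11 for the Gf 5′ UTR, 4 for the A 5′ UTR, 17 for ORF2, 76 for the IAP LTR, 8 for the IAP 5′ UTR, 6 for IAP gag, 3 for MusD and 18 for MERVL. The pair of L1 ORF1 was found in 0 transcripts, which left 9 segments. L1 and IAP denote the sums of their segments. Sense is the orientation of the transposon's own transcript. The ping-pong measure is the share of 10 nt among overlaps of 1 to 20 nt between 5′ ends on opposite strands.

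Each KO was compared with the WT of its line and age, the WT of the Dnmt3L line between ages, and the Miwi2 WT with the Dnmt3L WT at 10 dpp. No test was run, since each group is 1 library. Transcripts with at least 500 sense reads of piRNA size over the compared libraries were compared, and miRNAs with at least 1000 reads. A change was called where the absolute log2 ratio exceeded the 95th percentile of the absolute log2 ratios between both WT libraries of 10 dpp over items with the same count minimum. For transposon segments this limit, 2.14, rests on 17 of 18 segment and strand items and is a rough estimate. It served for the read classes too. Each alternative took its own limit in the same way, for segments 1.22 to 3.13 over 7 to 17 items, which was computed for segments after their values were seen. The 11 miRNA lists that mark germ and somatic cells of the testis, the size rule, the count minimums and the rule for named genes were fixed before the data were examined. That rule names the 10 windows with the most reads over all libraries, for each comparison the 5 families and 5 miRNAs with the largest rise and the 5 with the largest fall, and the members of the miRNA lists. It was applied to transcripts in place of windows, which added the 5 transcripts with the largest rise and fall per comparison. A list's median log2 ratio was set against 10000 random lists of the same size matched on expression, where it had at least 3 measured members. Random lists treat members as independent items, which those of a genomic cluster need not be. A list of epithelial miRNAs was added after the miRNA results were seen.

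Alternatives tried were scaling by miRNA reads, TMM factors of edgeR 4.0.16 (used for scaling only), a piRNA size of 25 to 30 nt, counting distinct sequences, tags of 1 transcript or 1 position only, no count minimum and a minimum of 2000 reads, thinning to the smallest library (28701563 reads), leaving out the 10 most abundant sequences, and for miRNAs scaling by all reads. Levels over distinct sequences were scaled to the library's total of distinct sequences instead of its reads. TMM factors were taken over the compared items themselves, which were transcripts, miRNAs or the 18 segment and strand items. Each KO was also compared with the WT of the other line and with the mean of both WT libraries at 10 dpp. The alternatives of 24 to 28 nt, exact primer matches, reads inside the primer-bounded part only, protein-coding transcripts only and transcripts without the segments' reads were added after the data were seen. The code was tested on simulated data. Matching found 2000 of 2000 drawn sequences at their positions with 0 wrong hits, and 3000 planted pairs of 10 nt overlap were counted as 2966 above a background of 5.06%. Of 50 simulated transcripts each with 8-fold higher and lower levels, the rule called all 50 in each KO comparison. It called 0 of 50 with 2-fold changes, so changes of that size cannot be seen. Both outcomes follow from the size of the limit, since counts were drawn with Poisson error only around transcripts of at least 500 reads. No spread between pools was simulated, so this does not show how reliable the calls are. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3.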

Results

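Small RNA was sequenced from whole mouse testis in 6 libraries of an 18 to 35 nt fraction. Each library was a single pool of C57BL/6 animals, and no group had a second library. Testes lacking Dnmt3L and their wild-type (WT) littermates were taken at 16.5 days post coitum (dpc), with 7 or 8 mice in each pool, and at 10 days post partum (dpp), with 3 mice in each pool. Testes lacking Miwi2 and their WT littermates were taken at 10 dpp, also with 3 mice in each pool. The Dnmt3L line gave 42370622 reads in the WT and 47232494 in the knockout (KO) at 16.5 dpc, and 38069968 and 28701563 at 10 dpp. The Miwi2 line gave 45010155 reads in the WT and 37218684 in the KO. Levels are given as RPM, reads scaled to a library of 1e6 reads. With 1 library per group, no difference has a replicate check. Intervals are 95% exact Clopper-Pearson intervals for shares, exact Poisson intervals for counts and exact conditional binomial intervals for ratios, and they cover counting error only, since reads without molecular identifiers are not independent molecules. A level of 3 counts corresponded to 0.0635 to 0.105 RPM across the libraries. A change was called only where its log2 size exceeded the 95th percentile of the log2 sizes between both WT libraries of 10 dpp. That limit was 2.02 for transcripts, 2.84 for microRNAs (miRNAs) and 2.14 for transposon segments, the last resting on 17 of 18 segment and strand items and therefore a rough estimate. Under TMM scaling, by trimmed means of the transcripts, the median log2 ratio between these WT libraries went from 0.88 to -0.13 and the transcript limit fell to 1.32, so a shift common to most transcripts widened it. For transposon segments TMM was taken over the 18 segment and strand items themselves, not over transcripts. Ratios over distinct sequences were scaled to the library's total of distinct sequences.

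The deleted genes left few reads. Dnmt3l (GRCm38 chromosome 10, 78041947 to 78063622), which encodes a cofactor of the de novo DNA methyltransferases, had 105 sense reads of piRNA size in the WT and 295 in the KO of its line at 16.5 dpc, 1 and 0 at 10 dpp, and 7 and 4 in the Miwi2 WT and KO. Piwil4 (chromosome 9, 14696230 to 14740733), the gene of the PIWI protein MIWI2, had 2 reads in the Miwi2 WT and 3 in the Miwi2 KO, and 14, 7, 9 and 2 in the Dnmt3L line (WT and KO at 16.5 dpc, then WT and KO at 10 dpp). Reads of 24 to 32 nt are short fragments whose place relative to the deleted part is not known, so these counts check none of the genotypes.

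Reads of piRNA size (24 to 32 nt) were the larger class of small RNA in fetal testis and the smaller one after birth. Their share of 18 to 35 nt reads was 48.1% in the Dnmt3L WT at 16.5 dpc and 21.4% at 10 dpp, while reads of miRNA size (20 to 23 nt) went from 39.5% to 75.2%. The fetal order depends on the size bound, since reads of 25 to 30 nt were 34.2% in the Dnmt3L WT at 16.5 dpc. In the Dnmt3L KO piRNA-size reads were 52.7% at 16.5 dpc and 14.5% of the 18 to 35 nt reads at 10 dpp. The Miwi2 WT and KO differed little, with 32.9% (95% interval 32.9 to 32.9) and 32.6% (32.6 to 32.6). Both Dnmt3L libraries of 10 dpp held few long reads. Reads of 30 nt were 0.283% of the WT and 0.0185% of the KO, against 2.08% and 2.31% in the Miwi2 WT and KO of the same age. Reads of 28 nt were 1.59% and 0.390% against 4.20% and 4.26%.

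Most piRNA-size reads started with U, the usual first base of piRNAs. The share with U at position 1 was 70.3% in the WT and 72.1% in the Dnmt3L KO at 16.5 dpc, 77.7% and 81.7% at 10 dpp, and 67.3% in both the Miwi2 WT and KO. The higher share of the Dnmt3L KO at 10 dpp turned lower at 25 to 30 nt (72.5% in the WT, 70.9% in the KO). A at position 10, the mark of secondary piRNAs made by the ping-pong cycle, stood at 29.98% and 28.9% at 16.5 dpc, 23.4% and 14.3% in the Dnmt3L WT and KO at 10 dpp, and 26.7% and 28.6% in the Miwi2 WT and KO. The share depends on which small RNAs fall in the size range. Reads of miRNA genes, 8.49% of which had A at position 10 in the Dnmt3L KO at 10 dpp, were 37.4% of its piRNA-size reads and 24.8% of those of the WT. At 25 to 30 nt the shares of A at position 10 in that line and age were 27.3% in the WT and 25.5% in the KO. At 16.5 dpc the direction reversed over distinct sequences (30.8% and 31.97%).

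**Figure D1:**
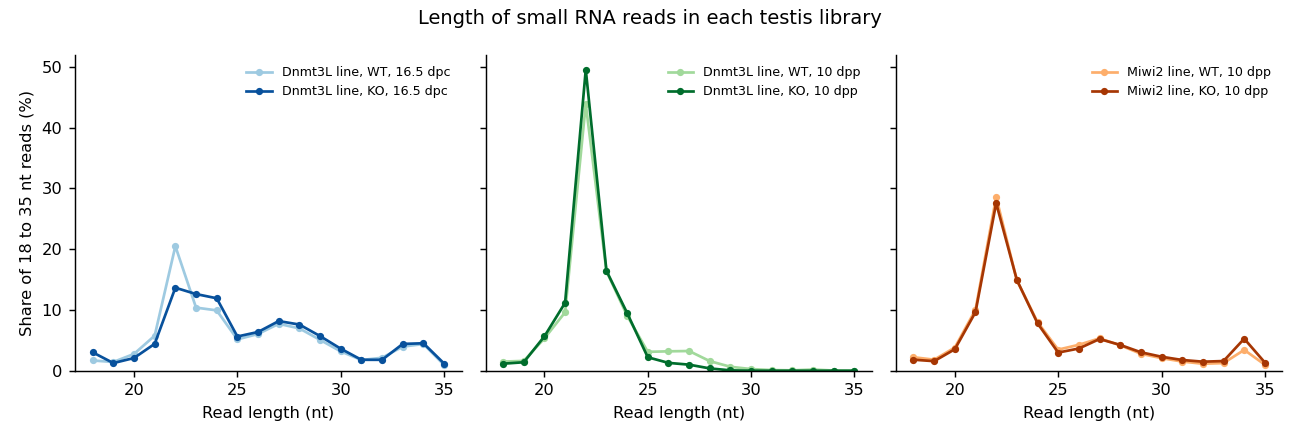
Length of small RNA reads. The x axis is read length in nt and the y axis the share of 18 to 35 nt reads in percent; each line is 1 library, in 1 panel per WT and KO pair with the KO in the darker colour. The 22 nt peak reached 49.6% in the Dnmt3L KO at 10 dpp and 13.7% in the Dnmt3L KO at 16.5 dpc.

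At 16.5 dpc, when transposons are methylated in fetal germ cells, the comparison asks whether the testis without Dnmt3L makes the same transposon piRNAs as the WT. L1 and IAP retrotransposon reads differed by less than both WT libraries of 10 dpp differed from each other. Reads of L1 segments were 14754 RPM in the KO and 14349 in the WT, 1.03-fold (95% interval 1.02 to 1.03). Reads of IAP segments, from an endogenous retrovirus, were 5149 and 5989 RPM, 0.860-fold (95% interval 0.855 to 0.865). No segment passed the size rule on either strand, and transcripts passed it only in Asb18, which rose, and Gm26870, which fell.

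By strand, L1 sense reads were 1.28-fold and L1 antisense reads 0.860-fold of the WT, so the sense share of L1 reads was 49.9% in the KO and 40.1% in the WT. Under TMM scaling the L1 sense log2 ratio was -0.098 instead of 0.36, and that of both strands together was -0.41 instead of 0.040. Counting only tags inside the primer-bounded part, the log2 ratio of L1 antisense reads was 0.32 instead of -0.22 and that of all IAP reads 0.26 instead of -0.22. The Tf 5′ UTR segment of L1 was at 1.08-fold, the Gf 5′ UTR at 0.689-fold, the A 5′ UTR at 1.02-fold and ORF2 at 1.13-fold. IAP sense reads were 0.993-fold and IAP antisense reads 0.748-fold of the WT. The long terminal repeat (LTR) of IAP was at 0.882-fold, its 5′ UTR at 0.812-fold and its gag segment at 0.754-fold. MusD and MERVL, which are further endogenous retroviruses, were at 1.15-fold and 0.942-fold. Under TMM the log2 ratios turned negative for the Tf 5′ UTR (-0.35), the A 5′ UTR (-0.42), ORF2 (-0.28) and MusD (-0.25). With reads inside the primer-bounded part only, that of MERVL was 1.76. With scaling by miRNA reads the log2 ratios turned positive for IAP sense reads (0.18), the IAP LTR (0.011) and MERVL (0.11).

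Of 1155 transcripts with at least 500 sense reads over both libraries, 1 rose and 1 fell, with a median log2 ratio of 0.00 (0.19 with scaling by miRNA reads). Asb18 (chromosome 1, 89950220 to 90014666) had 133 RPM in the KO and 27.6 in the WT, 4.83-fold, and 1.33% of its reads matched no other transcript. The lincRNA Gm26870 (chromosome 9, 3000282 to 3038313) had 0.127 and 13.4 RPM, 0.00948-fold. The next lowest ratios did not pass: 0.294-fold for Col1a2 and 0.315-fold for Col1a1, both chains of type I collagen, 0.295-fold for Rprml and 0.421-fold for the odorant receptor gene Olfr904. Neither did the next highest, at 3.58-fold for Adam12, 3.52-fold for Gm47646, 3.14-fold for Gm37900 and 2.60-fold for Gm40765, whose log2 ratio turned to -0.64 with tags of 1 transcript only and to -0.075 over distinct sequences. TMM scaling called 9 transcripts higher and 4 lower, and scaling by miRNA reads 0 and 1.

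Among 212 miRNAs, Mir410 rose 10.1-fold, from 814 to 8253 RPM of miRNA reads, and none fell. TMM called 3 miRNAs higher and 5 lower, and scaling by all reads 1 and 7. Mir410 belongs to the imprinted Dlk1-Dio3 cluster, in which the other 18 of 19 measured members did not pass and the median log2 ratio was 0.19. Mir323 of the same cluster was at 5.92-fold, Mir23b at 5.53-fold, Mir34b at 5.11-fold and Mir674 at 4.46-fold. The lowest ratios were those of Mir19b-1 (0.161-fold), Mir881 (0.162-fold), Mir19b-2 (0.163-fold), Mir19a (0.172-fold) and Mir5126 (0.175-fold), none past the rule. No measured member of the other fixed lists passed either. Their median log2 ratios were -0.34 over 4 miRNAs of the pluripotency clusters of Mir290 and Mir302, -0.26 over 7 of the proliferation-linked clusters of Mir17 and Mir106b, 0.94 over 2 miRNAs of the meiotic families of Mir34 and Mir449, 0.088 over 8 X-linked testis miRNAs and 0.28 over 12 let-7 miRNAs. For markers of somatic cells they were 1.03 for Mir202 of Sertoli cells, -0.33 over 5 peritubular and fibroblast miRNAs, -0.35 for endothelial Mir126a, -0.50 for erythroid Mir451a and 0.74 for haematopoietic Mir142.

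At 10 dpp, when transposon methylation has been missing since fetal life, the comparison asks what small RNA remains without Dnmt3L, and the KO had far fewer piRNA-size reads of gene transcripts. Reads sense to a transcript were 9427 RPM in the KO and 43457 in the WT, 0.217-fold (log2 -2.20). Over distinct sequences the log2 ratio was -0.81 after scaling to the library's total of them, which was 966003 in the KO and 2279855 in the WT. Unscaled, the distinct sequences sense to a transcript numbered 107891 and 447305. Of 613 transcripts, 502 fell and 9 rose, while of the 135 with at least 500 distinct sequences, counted once each, 53 fell and 3 rose by the limit of that count. Kif15, a kinesin motor gene, fell to 0.0177-fold, Bpnt1 to 0.0204-fold and the cell cycle kinase gene Cdk6 to 0.0261-fold of the WT. Sense reads of the L1 A 5′ UTR rose 6.86-fold at the same time, but missed the limit with scaling by miRNA reads (log2 2.53, limit 2.85) and with reads inside the primer-bounded part only (1.58, limit 3.13). The KO library also had the narrowest length range of all 6 libraries, with reads above 28 nt nearly missing.

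The transcripts that fell were mainly mRNAs read in their 3′ UTRs. Of the 502, 468 (93.2%) were protein coding, a median of 90.0% of the sense reads of those with a coding part lay in the 3′ UTR, and a median of 0.542% of reads were antisense. The place in the 3′ UTR was not particular to them, since its median was 85.0% in transcripts that did not pass, and 503 of the 613 tested transcripts were protein coding. Kif15 (chromosome 9, 122951046 to 123018733) had 0.488 RPM in the KO and 27.6 in the WT, and Bpnt1 (chromosome 1, 185332149 to 185357777) had 1.32 and 64.8. Cdk6 had 2.80 and 107, with 98.2% of its reads in the 3′ UTR. The lincRNA Gm40773 fell to 0.0235-fold and the small GTPase gene Rab11b to 0.0279-fold. Among the transcripts with the most reads over all libraries, Tmem38b, the gene of an intracellular cation channel, fell to 0.234-fold, D10Wsu102e to 0.229-fold, and Gm42418, a locus known to overlap ribosomal RNA sequence, to 0.196-fold. The largest rises were 5.96-fold in Gm42669, 5.84-fold in Gm48416, 5.42-fold in Gm37767, 5.17-fold in Gm47031 and 4.95-fold in Gm47654. Of the 9 transcripts that rose, 5 held reads of a transposon segment, as did 51 of the 102 that did not pass. The median transcript had a log2 ratio of -3.002 with scaling by all reads, -3.24 with scaling by miRNA reads and -0.39 with TMM, which centres the libraries on the transcripts themselves. Accordingly 428 transcripts were lower and 0 higher by miRNA reads, but 78 lower and 69 higher by TMM.

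Counted by reads, L1 and IAP segments changed less than genes. L1 segments had 301.9 RPM in the KO and 187 in the WT, 1.62-fold (95% interval 1.57 to 1.67), and IAP segments 518 and 787, 0.659-fold (95% interval 0.646 to 0.672), neither past the rule. Over distinct sequences, scaled to the library's total of them, the IAP log2 ratio of -0.60 was 0.73 and that of L1 was 1.09, with -0.81 for gene reads. That total was lower in the KO (966003 against 2279855 in the WT). It raises every ratio over distinct sequences given here alike, so their signs depend on the scaling too. L1 sense reads were 2.92-fold and antisense reads 0.509-fold of the WT, so 83.0% of L1 reads were sense in the KO and 46.0% in the WT. The sense ratio passed the setting's own limit in 3 of 8 alternatives, with log2 1.90 under TMM (limit 1.78), 1.52 over distinct sequences (limit 1.22) and 1.87 at 24 to 28 nt (limit 1.65). The antisense log2 ratio of -0.97 was 0.55 over distinct sequences and 0.23 with exact primer matches, which leave only the Tf and Gf segments in the sum. Sense reads of the L1 A 5′ UTR rose from 22.5 to 155 RPM, those of the Tf 5′ UTR were at 2.45-fold and those of the Gf 5′ UTR at 0.503-fold (log2 0.86 over distinct sequences). Antisense reads of IAP gag fell to 0.118-fold and those of MusD to 0.175-fold, past the limit in 5 of 7 and 5 of 8 alternatives. Over distinct sequences, scaled in that way, the log2 ratios were -0.18 and -0.10. The MusD fall also missed the limit with scaling by miRNA reads (-2.76, limit 2.85). MusD sense reads went the other way, past the limit in 2 of 8 alternatives, over distinct sequences and with thinned libraries. The sense share of MusD reads was 57.8% in the KO and 8.28% in the WT. On each strand MusD had fewer than 500 reads over both libraries, the minimum used for transcripts. Its ratios and shares here therefore rest on few reads. The IAP LTR was at 0.677-fold and MERVL at 0.335-fold, but over distinct sequences their log2 ratios were 0.69 and 0.38. The ratios also depended on read length. At 24, 25, 26, 27 and 28 nt L1 sense reads were at 4.96, 6.26, 4.90, 2.82 and 1.54-fold of the WT. IAP antisense reads were at 0.946, 1.31, 0.991, 0.795 and 0.383-fold, and gene reads at 0.261, 0.266, 0.251, 0.220 and 0.183-fold. Each of these ratios over 24 to 32 nt was below its values at 24 to 26 nt. The miRNA fraction read within 24 to 32 nt was at 1.07-fold, other small RNA at 0.401-fold and reads of repeat-like sequence at 0.325-fold. Over distinct sequences the repeat-like log2 ratio was 0.35 after scaling, although unscaled they numbered 8441 in the KO and 15652 in the WT.

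Of 227 miRNAs, 2 rose and 5 fell, around a median log2 ratio of 0.40 that was 0.11 under TMM. Mir449a, of a family known from meiotic and ciliated cells, rose 25.7-fold, from 4.94 to 127.2 RPM of miRNA reads, and the epithelial miRNA Mir141 rose 7.94-fold. Mir375, at 7.04-fold, Mir205, at 5.97-fold, and Mir34c, at 3.20-fold, did not pass. Mir3470b fell to 0.0769-fold, Mir3470a to 0.0799-fold, Mir1195 to 0.0868-fold, Mir5098 to 0.0963-fold and Mir1954 to 0.0971-fold. The miRNA class came before the repeat-like class, so a read of a miRNA gene stayed there even if many other genes held it. Whether the reads of these 5 genes are mature miRNAs or pieces of repeated sequence was not examined, so their falls may not be changes of miRNAs. None of 15 measured X-linked testis miRNAs passed, but all had ratios below 1, with log2 ratios from -1.99 to -0.77, and the list's median of -1.39 lay below all 10000 random lists of the same size and expression. Members of a list can move together, and random lists do not allow for that. The let-7 family had a median of 0.66 (12 measured, percentile 98.1) and the Dlk1-Dio3 cluster one of 0.70 (21 measured, percentile 98.9), again with no member past the rule. The median was 3.18 for Mir449a and Mir34c, 0.25 for the proliferation clusters (-0.041 under TMM), and -0.25 for the single pluripotency miRNA measured. Somatic markers were at 0.50 (Mir202), 0.78 (peritubular and fibroblast), 0.090 (Mir126a, -0.20 under TMM), 0.84 (erythroid) and 0.29 (haematopoietic).

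**Figure D2:**
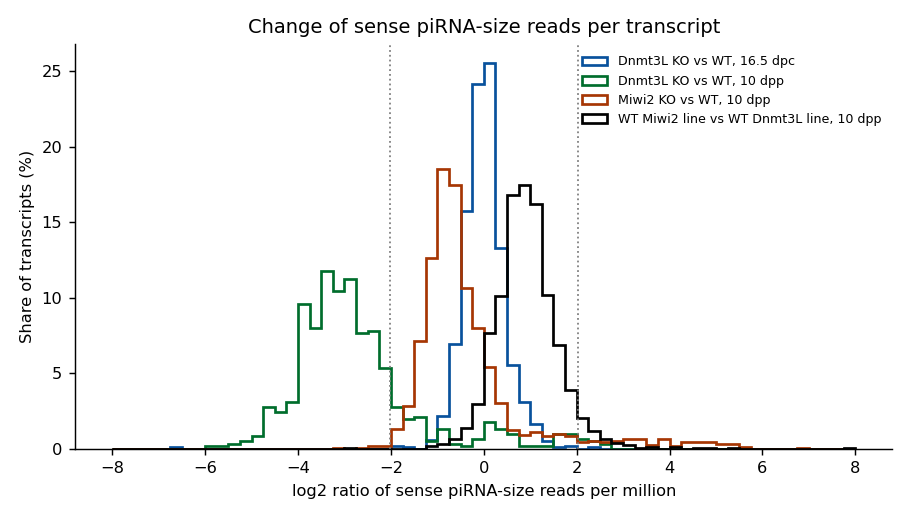
Change of sense piRNA-size reads per transcript. The x axis is the log2 ratio of RPM and the y axis the share of tested transcripts in percent; each outline is 1 comparison, and dotted lines mark the limit of the size rule, 2.02 in either direction. The Dnmt3L KO at 10 dpp has its median at -3.002 and the Miwi2 KO at -0.65.

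The Miwi2 comparison at 10 dpp asks what small RNA the testis makes without the nuclear PIWI protein MIWI2. L1 piRNA-size reads rose in the KO, past the limit of each scaling tried. The sum of gene reads lay near the WT level, although the median transcript was at 0.639-fold and 79.1% of transcripts had a log2 ratio below 0 (0.924-fold and 58.2% under TMM). L1 segments had 2318 RPM in the KO and 287 in the WT, 8.09-fold (95% interval 7.94 to 8.24). L1 sense reads rose 13.6-fold, from 135 to 1841 RPM. IAP segments had 4619 and 1542 RPM, 2.995-fold (95% interval 2.97 to 3.02), which did not pass the rule. Reads sense to a transcript were 71138 RPM in the KO and 73378 in the WT. Of 1666 transcripts, 107 rose and 8 fell, and 71 of those that rose held reads of a transposon segment. Without the reads of the segments 95 rose and 8 fell.

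Among L1 segments, the A 5′ UTR rose 10.1-fold and its sense reads 21.5-fold. The Tf 5′ UTR rose 8.72-fold, with 10.8-fold on the sense and 5.77-fold on the antisense strand. The antisense rise missed the limit under TMM (log2 1.42, limit 1.78), with scaling by miRNA reads (2.56, limit 2.85) and inside the primer-bounded part (2.54, limit 3.13). ORF2 rose 8.03-fold, with 13.7-fold on the sense strand, and the Gf 5′ UTR was at 0.633-fold (log2 0.028 over distinct sequences). Gf sense reads passed the limit as a fall in 1 of 8 alternatives, under TMM (log2 -2.30, limit 1.78). L1 antisense reads were at 3.16-fold, so the sense share of L1 reads was 79.4% in the KO and 47.3% in the WT. IAP antisense reads were at 3.90-fold and sense reads at 2.10-fold, the latter with a log2 ratio of -0.038 under TMM against 1.07. The IAP LTR was at 4.13-fold on the antisense strand, the IAP 5′ UTR at 3.50-fold, IAP gag at 1.71-fold, MusD at 1.51-fold and MERVL at 0.647-fold, none past the rule. Under TMM the log2 ratios of IAP gag and MusD turned to -0.34 and -0.52. Over distinct sequences, scaled to their library total, the L1 log2 ratio was 1.49 and under TMM scaling 1.91, against 3.02. This TMM was taken over the segment items, L1 among them, so it removes part of a change they share. Both log2 ratios were past the limit taken in the same way within each setting, 1.22 over 8 items and 1.78 over 17. With reads inside the primer-bounded part only, the log2 ratio of 2.32 was below the limit of 3.13, which rests on 7 items.

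**Figure D3:**
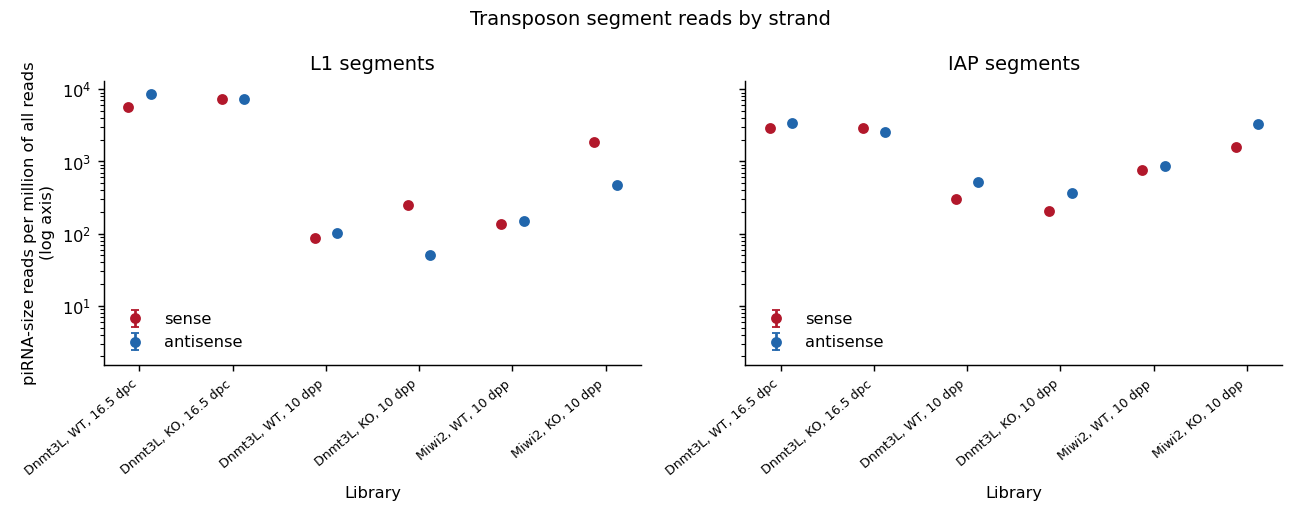
piRNA-size reads of L1 and IAP segments by strand. The x axis lists the 6 libraries and the log y axis gives RPM; points are libraries and bars 95% exact Poisson intervals, mostly smaller than the points. L1 sense reads were at 5748 RPM in the Dnmt3L WT at 16.5 dpc, 135 in the Miwi2 WT and 1841 in the Miwi2 KO.

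Many reads of the transcripts that rose in the Miwi2 KO also matched other transcripts. Of the 107, 19 were protein coding, a median of 30.1% of their reads were antisense and a median of 5.22% matched no other transcript. With only tags of 1 transcript, 23 rose and 13 fell. Nrros (chromosome 16, 32142785 to 32165594), which encodes a transmembrane protein that binds latent TGF-beta, rose 112-fold, from 0.267 to 29.8 RPM, and 99.9% of its reads matched no other transcript. Ky (chromosome 9, 102505750 to 102546239) rose 45.7-fold with all its reads from 1 transcript. Gm21962 rose 51.1-fold, the pseudogene Gm48416 42.8-fold and Vps35, a gene of the retromer complex, 43.9-fold. Only 1.71% of Vps35 reads matched no other transcript, and those alone gave a log2 ratio of -1.14. Noct rose 7.47-fold, from 404 to 3019 RPM, Gm42860 5.91-fold, Gm35240 7.57-fold and Gm48309 11.2-fold, all 4 among the transcripts with the most reads over all libraries. D10Wsu102e was at 0.954-fold and Tmem38b at 1.04-fold. The 8 transcripts that fell were protein coding. They included the zinc finger gene Zfp317 (0.112-fold), Nop16 (0.172-fold), Zyg11a (0.183-fold), Xkrx (0.190-fold) and Tapbp (0.200-fold), the gene of tapasin, which loads peptides onto MHC class I. The median log2 ratio was -0.65, and -0.11 under TMM, which called 185 higher and 17 lower. Scaling by miRNA reads called 84 and 1.

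Of 242 miRNAs, Mir449a fell to 0.0591-fold, from 153.6 to 9.08 RPM of miRNA reads, and its neighbour Mir449c to 0.0785-fold, while none rose. Mir375 was at 0.201-fold, Mir221 at 0.443-fold and Mir378a at 0.479-fold. The highest ratios were those of Mir466f-2 (3.68-fold), Mir463 (3.01-fold), Mir201 (2.71-fold), Mir878 (2.56-fold) and Mir877 (2.43-fold), none past the rule. None of 17 X-linked testis miRNAs passed, and their median log2 ratio of 0.85 lay above all 10000 random lists. The 20 measured miRNAs of the Dlk1-Dio3 cluster had a median of -0.50, below all random lists, and the meiotic families of Mir34 and Mir449 one of -3.67, with 2 of 3 lower. Between the WT libraries of both lines these lists had medians of 0.68 (percentile 17.2), 1.17 (percentile 88.1) and 4.96 (percentile 99.95), against 0.91 over all miRNAs. Of these only the meiotic list stood apart from the random lists there. Members of a list can move together, which random lists do not allow for. The other KO medians were -0.53 for the pluripotency clusters, 0.14 for the proliferation clusters, 0.20 for let-7, 0.75 for Mir202, -0.13 for peritubular and fibroblast miRNAs, 0.70 for Mir126a and 0.15 for the haematopoietic miRNAs. No erythroid miRNA reached 1000 reads.

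At 10 dpp the Miwi2 KO gained more L1 reads over its WT than the Dnmt3L KO did over its own. The log2 ratio of L1 segments was larger by 2.32 (95% interval 2.27 to 2.37) in the Miwi2 line and that of IAP segments by 2.18 (95% interval 2.15 to 2.22). These differences were 0.86 and 0.73 under TMM, which centres the libraries on the segments themselves. Over distinct sequences, scaled to the library's total of them, they were 0.41 and 0.23. Between both WT libraries L1 differed 1.54-fold and IAP 1.96-fold. The L1 sense and IAP antisense ratios of the Dnmt3L KO fell from 25 to 28 nt, and its library held few longer reads. The differences between the lines therefore depend on the lengths counted. Ratios by single length were not computed for the Miwi2 KO. Within the Dnmt3L line, the L1 log2 ratio at 10 dpp exceeded that at 16.5 dpc by 0.65 (95% interval 0.61 to 0.70), and the IAP log2 ratio differed by -0.38 (95% interval -0.41 to -0.35), which was 0.42 under TMM and 0.89 over distinct sequences. The L1 difference was 0.060 with reads inside the primer-bounded part only, and 1.46 under TMM. Of 612 transcripts tested in both KO comparisons of 10 dpp, all 9 that rose in the Dnmt3L KO were among the 45 that rose in the Miwi2 KO. The reads of these transcripts were mostly shared with others (a median of 0.281% in the Dnmt3L comparison matched no other transcript), so they are not independent items, and with tags of 1 transcript only 2 rose in the Dnmt3L KO. The comparisons share no library.

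Sense and antisense reads overlapped by 10 nt at their 5′ ends, the signature of ping-pong amplification, in every library when counted by reads. On L1 segments overlaps of 10 nt were 14.3% of overlaps of 1 to 20 nt in the WT and 13.9% in the Dnmt3L KO at 16.5 dpc, 12.5% and 19.9% in the Dnmt3L WT and KO at 10 dpp, and 13.7% and 17.9% in the Miwi2 WT and KO. The gain of the Miwi2 KO was 4.19 percentage points over reads, 0.0208 at 24 to 28 nt and -1.63 over distinct sequences. That of the Dnmt3L KO at 10 dpp was 7.40 over reads and 0.729 over distinct sequences. At 16.5 dpc the L1 share over distinct sequences was 6.13% in the WT and 5.88% in the KO, little above the highest share of another overlap length, 5.57% and 5.71%. L1 overlaps over distinct sequences numbered 27234 and 35988 there, against 1704 and 6491 in the Miwi2 WT and KO. This count ignores how many reads a sequence has, so dense coverage can make all overlap lengths look alike. A low share over distinct sequences therefore need not mean weak ping-pong, which was not tested. On IAP segments the share was 10.1% and 10.4% at 16.5 dpc, 13.9% and 10.5% in the Dnmt3L WT and KO at 10 dpp, and 13.4% and 11.1% in the Miwi2 WT and KO. Over distinct sequences it was 6.79% and 6.50% at 16.5 dpc, which reversed the direction, 9.07% and 8.86% in the Dnmt3L line at 10 dpp, and 8.52% and 7.55% in the Miwi2 line. On other transcripts it ranged from 11.3% to 14.5%.

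**Figure D4:**
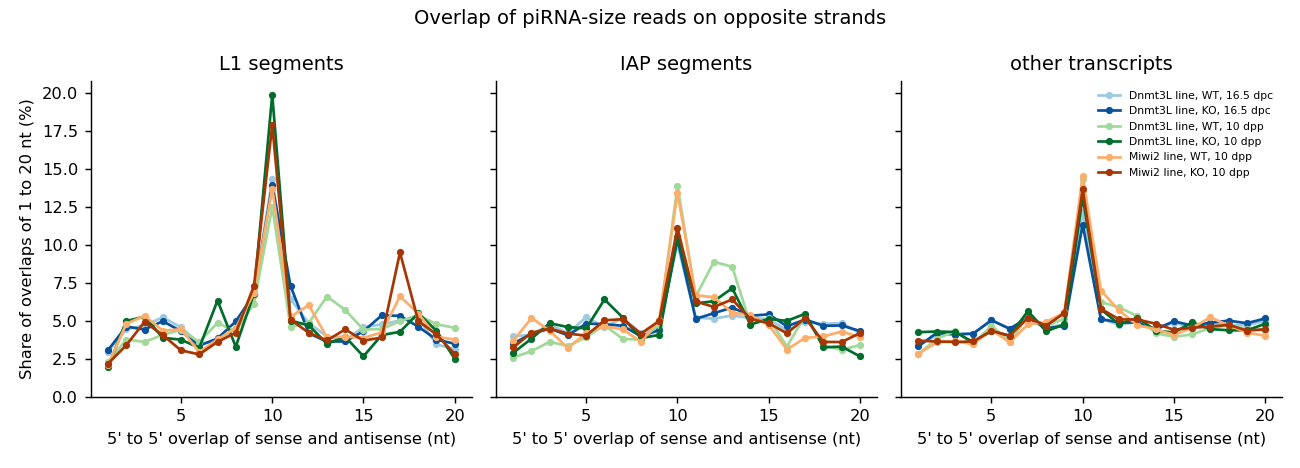
Overlap of piRNA-size reads on opposite strands. The x axis is the overlap of 5′ ends in nt and the y axis its share of overlaps of 1 to 20 nt in percent; each line is 1 library, in panels for L1 segments, IAP segments and other transcripts. At 10 nt the lines on L1 segments lie between 12.5% and 19.9%.

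The age comparison, within the WT of the Dnmt3L line, asks how small RNA changes between 16.5 dpc and 10 dpp. Transposon piRNAs fell and piRNAs of many mRNAs rose. L1 reads fell to 0.0130-fold, from 14349 to 187 RPM. IAP reads fell to 0.131-fold. Of 1169 transcripts, 404 rose and 444 fell. Of those that rose, 393 (97.3%) were protein coding, and 179 of those that fell (40.3%) held reads of a transposon segment. Gm7968 fell from 2125 to 1.78 RPM, Gm35240 from 1718 to 1.48, and Gm48309 from 989.9 to 14.7. Antisense reads of IAP gag, at 0.364-fold, did not pass the rule, whereas each other segment and strand fell. With scaling by miRNA reads 126 transcripts were higher and 482 lower, and with TMM 457 and 530. The number of mice per pool, the read length and the length range of the library also differed between these libraries.

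Of 229 miRNAs, 12 rose and 29 fell with age, against 50 and 14 with scaling by all reads and 27 and 31 with TMM. The X-linked testis miRNAs rose in 9 of 14 measured members, with a median log2 ratio of 3.10 above all random lists. They were led by Mir743 (25.1-fold), Mir463 (23.6-fold), Mir883a (21.4-fold) and Mir743b (20.4-fold). Outside that list Mir1195 rose 19.9-fold, but whether its reads are mature miRNA or pieces of repeated sequence was not examined. All 4 measured pluripotency miRNAs fell, with a median of -3.84, Mir291a to 0.0439-fold. In the Dlk1-Dio3 cluster 4 of 18 fell, Mir433 to 0.0289-fold, with a median of -0.97. Mir5126 fell to 0.0141-fold, Mir667 to 0.0191-fold and Mir370 to 0.0491-fold. Mir34c, the only measured member of the meiotic families, fell with a log2 ratio of -3.06. No member passed in the other lists, whose medians were -1.14 for the proliferation clusters, 1.05 for let-7, 1.95 for Mir202, -0.33 for peritubular and fibroblast miRNAs, -0.11 for Mir126a, -1.74 for the erythroid and 0.98 for the haematopoietic miRNA measured.

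Both WT libraries of 10 dpp, from different lines, gave the only control against control comparison. The Miwi2 WT had 1.54-fold the L1 reads and 1.96-fold the IAP reads of the Dnmt3L WT. Reads sense to a transcript were 1.69-fold, and 73 of 1473 transcripts lay above the limit and 1 below it, with a median log2 ratio of 0.88. Under TMM that median was -0.13, with 41 above and 33 below the limit of that scaling. The limit was this comparison's own 95th percentile, so about 5% of its items passed by construction and these passes are no finding. Sense reads of the L1 Gf 5′ UTR, at 4.91-fold, were past the segment limit in the same way. Those of MusD, at 4.49-fold, were also past it, but had fewer than 500 reads and took no part in setting it. Mir449c, at 68.0-fold, Mir449a, at 31.1-fold, Mir205, at 11.1-fold, Mir744, at 10.9-fold, and Mir877, at 10.8-fold, differed most among miRNAs. Mir449a differed at least as much between the WT pools as between either KO and its WT.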

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

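The tests of size selection, scaling, even cell loss, degraded RNA and a library-wide gain were chosen only after the result was seen. That of size selection was divided by read length after its values were known. Those of a few abundant sequences and of duct epithelium were fixed before their values were computed, but the duct test also used a condition outside its fixed rule. With 1 library per group none of the differences between comparisons given here was tested.

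Some effects had opposite signs in the KO comparisons of 10 dpp. The log2 ratio of the Miwi2 comparison exceeded that of the Dnmt3L comparison by 2.63 for L1 antisense reads, 1.66 for IAP sense reads, 2.46 for IAP antisense reads, 2.74 for repeat-like reads and 1.90 for reads antisense to transcripts. Within the Dnmt3L line the log2 ratio moved by -2.81 from 16.5 dpc to 10 dpp for MusD antisense reads, -1.64 for repeat-like reads, -2.22 for reads sense to transcripts and -1.65 for reads antisense to transcripts. The differences were not tested. MusD antisense reads at 10 dpp were fewer than 500 over both Dnmt3L libraries, so the value of -2.81 rests on few reads. The IAP sense ratio of the Miwi2 KO was -0.038 under TMM, so its opposite sign ended there. Over distinct sequences the log2 ratios of the Dnmt3L KO at 10 dpp turned positive for L1 antisense (0.55), IAP sense (0.79), IAP antisense (0.73) and repeat-like reads (0.35), which ended their opposite signs to the Miwi2 KO. These ratios were scaled to the library's total of distinct sequences, which was lower in this KO (966003 against 2279855), so the turns depend on the scaling too. Unscaled, repeat-like sequences numbered 8441 in this KO and 15652 in its WT. With exact primer matches the L1 antisense log2 ratio of this KO was 0.23. Within the Dnmt3L line the signs also met for MusD antisense reads under TMM (-0.16 at 16.5 dpc), and for reads sense to transcripts over distinct sequences and at 24 to 28 nt (-0.050 and -0.046 at 16.5 dpc). The repeat-like signs of that line swapped over distinct sequences (-0.17 at 16.5 dpc) only after scaling. At 16.5 dpc these sequences numbered 40387 in the KO and 34645 in the WT, and the totals they were scaled to were 6478621 and 4951907. Reads of 33 to 34 nt, outside the piRNA size, made up 8.95% of 18 to 35 nt reads in the Dnmt3L KO against 8.38% in the WT at 16.5 dpc, and 6.88% in the Miwi2 KO against 4.70% in the WT. In the Dnmt3L line at 10 dpp they were 0.245% in the WT and 0.0165% in the KO. Their source was not examined.

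The first pattern weighed is the lower level of gene reads of piRNA size in the Dnmt3L KO at 10 dpp. Scaling by miRNA reads gave a log2 ratio of -2.45, a larger fall, although the limit of that scaling is 2.85. This cannot decide whether scaling by all reads plays a part, since miRNA reads were most of both libraries. They were 24282734 of 38069968 reads in the WT and 21657588 of 28701563 in the KO, so both scales move nearly together. TMM, not run for the read classes, moved the median transcript from -3.002 to -0.39, but it centres the libraries on the transcripts themselves. An even loss of all piRNA-producing cells alone would move gene and IAP reads alike, but the ratio of IAP antisense reads was 3.28 times that of gene reads. The quotient cannot exclude an even loss together with a gain of IAP reads, and the quotients by length below share this limit. Other reads lay on both sides of the gene log2 ratio of -2.20. IAP gag and MusD antisense reads were at -3.08 and -2.51, the latter from fewer than 500 reads over both libraries. Repeat-like reads and reads antisense to transcripts were at -1.62 and -1.57. Tighter size selection of the KO library acts alike on all reads of a length, but at 26 and 27 nt the gene ratio was 0.253 and 0.276 of the IAP antisense ratio, and it could be part of the cause at 28 nt, where the quotient of 0.478 had an interval up to 0.520 and passed the bound of 0.5. Other small RNA of piRNA size also fell, to a log2 ratio of -1.32, while reads of miRNA genes of that size were at 0.094. The fall was thus not limited to gene transcripts, and a difference between the libraries or pools other than genotype stays open. A loss of the germ cells that carry gene piRNAs, or of those piRNAs within cells that keep IAP piRNAs, stays open too, as a consequence of the genotype. The miRNA lists bear on it without deciding it. In this KO the X-linked testis miRNAs had a median log2 ratio of -1.39 (all 15 measured below 0, below all random lists), while the let-7 family and the peritubular and fibroblast miRNAs lay at 0.66 and 0.78 (percentiles 98.1 and 99.4). A smaller share of some germ cells would move the lists this way, but no X-linked member passed the size rule, and the ratios of Mir449a and Mir34c, of the meiotic families, were above 1 (median log2 3.18). Members of a list can move together, so percentiles among random lists can overstate how unusual it is. Between the WT pools the let-7 and the peritubular and fibroblast medians were 0.63 and 0.54 (percentiles 52.0 and 30.1). That of the meiotic families was 4.96 (percentile 99.95), so these miRNAs differed between pools without a KO and cannot weigh on this question.

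The second pattern is the rise of L1 sense reads in the Miwi2 KO at 10 dpp. Fragments of degraded L1 RNA are argued against, since the share with U at position 1 exceeded the mean share at positions 2 to 9 by 53.9 percentage points (70.7% and 16.8%). A few abundant sequences do not account for it alone, since without the 10 most abundant, which held 27.4% of these reads, the fold was still 10.99 (95% interval 10.7 to 11.3), although over distinct sequences the log2 ratio was 1.71 instead of 3.76. A library-wide gain of piRNA-size reads is argued against by a ratio of 0.635 for MERVL sense reads. More L1 transcripts entering the piRNA pathway without MIWI2 may be the source, as a hypothesis found and viewed in the same libraries. L1 RNA levels in further pools of both genotypes would decide it and are not among these data. A difference between the pools other than genotype cannot be excluded.

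The third pattern is Mir449a, higher in the Dnmt3L KO and lower in the Miwi2 KO than in each WT. Epithelium of the ducts in some of the pools may be its source. It was tested with 5 epithelial miRNAs, Mir200a, Mir200b, Mir200c, Mir429 and Mir203, of which 4 were measured and none is in another list used here. Their median log2 ratio was 0.77 in the Dnmt3L comparison (range -0.32 to 1.06) and 0.47 in the Miwi2 comparison (range -0.28 to 0.78), within the bound of 0.5 set beforehand for exclusion. By that rule alone duct epithelium would be excluded, and the Miwi2 median was opposite in sign to the predicted fall. The matter was left undecided by a further condition on marker levels that was not part of the rule set beforehand. All 4 are present in the libraries with little Mir449a, at a median of 107 RPM of miRNA reads in the Dnmt3L WT and 148 in the Miwi2 KO. Mir449a itself had 127.2 RPM in the Dnmt3L KO and 153.6 in the Miwi2 WT, and its ratio to the 4 miRNAs in duct cells is not known here, so such levels could hide duct cells. Mir141 and Mir375, known from epithelia, are outside the list. Mir375 was at 7.04-fold in the Dnmt3L KO and 0.201-fold in the Miwi2 KO. Mir141 was at 7.94-fold in the Dnmt3L KO, and in the Miwi2 line, with fewer than 1000 reads and so not compared, it had 14.5 RPM in the KO and 36.0 in the WT. Both were taken from the largest changes seen, so they test nothing. Mir449a also differed between both WT pools, at least as much as between either KO and its WT, so a difference of that size arose without a KO. An effect of the genotypes stays open and untested, and so does dissection.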

How the results depend on the processing

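The alternatives of 24 to 28 nt, exact primer matches only, reads inside the primer-bounded part only, protein-coding transcripts only, and transcripts without the segments' reads, were chosen after seeing the data. No paired analysis was possible because each group is 1 pool. TMM was not run for the read classes, and leaving out a library would leave a group empty. Positive under every alternative run for them were the log2 ratios of the Miwi2 KO for L1 reads (1.49 to 3.19, 7 of 8 past the limit of the alternative), L1 sense reads (1.71 to 3.88, 7 of 8) and IAP reads (0.47 to 1.85, 1 of 8), and of the Dnmt3L KO at 10 dpp for sense reads of the L1 A 5′ UTR (1.58 to 3.13, 5 of 7), a segment that exact primer matches did not find. Gene sense reads of that KO stayed lower (-2.45 to -0.81, 2 of 5 past the limit). They missed it with scaling by miRNA reads and with thinned libraries because the limit rose to 2.85 and 2.25. Over distinct sequences the ratio was -0.81, below the limit of 1.22. There the scale changed too, to the library's total of distinct sequences (966003 in the KO and 2279855 in the WT). Mir449a stayed higher there (4.40 to 4.93) and lower in the Miwi2 KO (-4.16 to -4.07). The L1 ratios of the Miwi2 KO missed the limit of 3.13 with reads inside the primer-bounded part only, and IAP reads passed a limit, 1.65, at 24 to 28 nt only. Directions at 16.5 dpc and of IAP in the Dnmt3L KO changed between alternatives.

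In all, 145 values of the main comparisons moved by more than their counting interval or 1.5 times, 10 reversed and 73 did neither; among single genes, segments and lists these numbers were 606, 7 and 535. Of all 138 log2 ratios and differences of the main comparisons, 7 more changed sign without having been called, and of 1148 others 73 did. The values follow, and the cause was not tested unless given.

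With scaling by miRNA reads, log2 ratios were gene sense reads 0.21 (16.5 dpc), -2.45 (Dnmt3L KO, 10 dpp), -0.012 (Miwi2 KO), L1 reads 0.23 (16.5 dpc), 0.45 (Dnmt3L KO, 10 dpp), 3.05 (Miwi2 KO) and IAP reads -0.026 (16.5 dpc), -0.84 (Dnmt3L KO, 10 dpp), 1.61 (Miwi2 KO). Differences of log2 ratios were, for the L1 ratio of the Dnmt3L line at 10 dpp minus that at 16.5 dpc 0.22, the same for IAP -0.82, the Miwi2 minus the Dnmt3L ratio 2.60 for L1 and 2.46 for IAP. The counts were transcripts higher 0 (16.5 dpc), 0 (Dnmt3L KO, 10 dpp) and transcripts lower 1 (Miwi2 KO). With TMM scaling, log2 ratios were L1 reads -0.41 (16.5 dpc), 1.04 (Dnmt3L KO, 10 dpp), 1.91 (Miwi2 KO) and IAP reads -0.67 (16.5 dpc), -0.25 (Dnmt3L KO, 10 dpp), 0.47 (Miwi2 KO). Differences of log2 ratios were, for the L1 ratio of the Dnmt3L line at 10 dpp minus that at 16.5 dpc 1.46, the same for IAP 0.42, the Miwi2 minus the Dnmt3L ratio 0.86 for L1 and 0.73 for IAP. The counts were transcripts higher 9 (16.5 dpc), 69 (Dnmt3L KO, 10 dpp), 185 (Miwi2 KO), transcripts lower 4 (16.5 dpc), 78 (Dnmt3L KO, 10 dpp), 17 (Miwi2 KO), miRNAs higher 3 (16.5 dpc) and miRNAs lower 5 (16.5 dpc). TMM also reversed the list medians of the Dnmt3L KO at 10 dpp for the proliferation clusters (-0.041) and Mir126a (-0.20). TMM centres each library on the compared items, so a shift shared by most of them is removed by construction. With miRNAs scaled by all reads, the counts were miRNAs higher 4 (Dnmt3L KO, 10 dpp) and miRNAs lower 7 (16.5 dpc).

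At 25 to 30 nt, log2 ratios were gene sense reads 0.022 (16.5 dpc), -2.22 (Dnmt3L KO, 10 dpp), -0.079 (Miwi2 KO) and IAP reads -0.23 (16.5 dpc), 1.57 (Miwi2 KO). The counts were transcripts lower 16 (Miwi2 KO). KO minus WT differences in percentage points were piRNA-size reads 2.95 (16.5 dpc), -7.09 (Dnmt3L KO, 10 dpp), -0.659 (Miwi2 KO), U at position 1 1.07 (16.5 dpc), -1.65 (Dnmt3L KO, 10 dpp), -0.317 (Miwi2 KO), A at position 10 -0.458 (16.5 dpc), -1.86 (Dnmt3L KO, 10 dpp), 2.86 (Miwi2 KO) and 10 nt overlaps on L1 2.97 (Dnmt3L KO, 10 dpp). The shares of U at position 1 reversed at 10 dpp. At 24 to 28 nt, log2 ratios were gene sense reads -0.046 (16.5 dpc), -2.11 (Dnmt3L KO, 10 dpp), -0.16 (Miwi2 KO), L1 reads -0.077 (16.5 dpc), 1.09 (Dnmt3L KO, 10 dpp), 3.11 (Miwi2 KO) and IAP reads -0.25 (16.5 dpc), -0.42 (Dnmt3L KO, 10 dpp), 1.85 (Miwi2 KO). Differences of log2 ratios were, for the L1 ratio of the Dnmt3L line at 10 dpp minus that at 16.5 dpc 1.17, the same for IAP -0.16, the Miwi2 minus the Dnmt3L ratio 2.02 for L1 and 2.27 for IAP. The counts were transcripts higher 3 (16.5 dpc), 17 (Dnmt3L KO, 10 dpp) and transcripts lower 62 (Miwi2 KO). KO minus WT differences in percentage points were 10 nt overlaps on L1 -0.552 (16.5 dpc), 0.0208 (Miwi2 KO) and 10 nt overlaps on other transcripts 0.472 (Miwi2 KO). The overlaps on other transcripts reversed.

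Over distinct sequences, log2 ratios were gene sense reads -0.050 (16.5 dpc), -0.81 (Dnmt3L KO, 10 dpp), -0.084 (Miwi2 KO), L1 reads -0.12 (16.5 dpc), 1.09 (Dnmt3L KO, 10 dpp), 1.49 (Miwi2 KO) and IAP reads -0.16 (16.5 dpc), 0.73 (Dnmt3L KO, 10 dpp), 0.96 (Miwi2 KO). Differences of log2 ratios were, for the L1 ratio of the Dnmt3L line at 10 dpp minus that at 16.5 dpc 1.21, the same for IAP 0.89, the Miwi2 minus the Dnmt3L ratio 0.41 for L1 and 0.23 for IAP. The counts were transcripts higher 0 (16.5 dpc), 3 (Dnmt3L KO, 10 dpp), 15 (Miwi2 KO) and transcripts lower 0 (16.5 dpc), 53 (Dnmt3L KO, 10 dpp), 1 (Miwi2 KO). KO minus WT differences in percentage points were piRNA-size reads 2.63 (16.5 dpc), -19.7 (Dnmt3L KO, 10 dpp), -3.57 (Miwi2 KO), U at position 1 0.538 (16.5 dpc), -8.70 (Dnmt3L KO, 10 dpp), -2.84 (Miwi2 KO), A at position 10 1.22 (16.5 dpc), -1.08 (Dnmt3L KO, 10 dpp), 1.22 (Miwi2 KO), 10 nt overlaps on L1 0.729 (Dnmt3L KO, 10 dpp), -1.63 (Miwi2 KO), 10 nt overlaps on IAP -0.287 (16.5 dpc), -0.204 (Dnmt3L KO, 10 dpp), -0.967 (Miwi2 KO) and 10 nt overlaps on other transcripts 0.455 (Dnmt3L KO, 10 dpp). Reversed were the IAP difference within the Dnmt3L line, both 10 dpp shares of U at position 1, the share of A at position 10 at 16.5 dpc, and overlaps on L1 in the Miwi2 KO, on IAP at 16.5 dpc and on other transcripts. Fewer transcripts reach 500 distinct sequences, which lowers their counts by construction. The log2 ratios were scaled to each library's total of distinct sequences. That total was lower in the Dnmt3L KO at 10 dpp than in its WT, which raises these ratios.

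With exact primer matches only, log2 ratios were L1 reads 0.077 (16.5 dpc), 1.19 (Dnmt3L KO, 10 dpp), 3.19 (Miwi2 KO) and IAP reads -0.31 (16.5 dpc), -0.27 (Dnmt3L KO, 10 dpp), 1.82 (Miwi2 KO). Differences of log2 ratios were, for the L1 ratio of the Dnmt3L line at 10 dpp minus that at 16.5 dpc 1.11, the same for IAP 0.039, the Miwi2 minus the Dnmt3L ratio 1.996 for L1 and 2.09 for IAP. The IAP difference within the Dnmt3L line reversed. Among L1 and IAP segments, exact matches were found only for the Tf and Gf 5′ UTR, the IAP LTR and the IAP 5′ UTR, so both sums lost members by construction. With reads inside the primer-bounded part only, log2 ratios were L1 reads 0.39 (16.5 dpc), 0.45 (Dnmt3L KO, 10 dpp), 2.32 (Miwi2 KO) and IAP reads 0.26 (16.5 dpc), -0.26 (Dnmt3L KO, 10 dpp), 1.11 (Miwi2 KO). Differences of log2 ratios were, for the L1 ratio of the Dnmt3L line at 10 dpp minus that at 16.5 dpc 0.060, the same for IAP -0.52, the Miwi2 minus the Dnmt3L ratio 1.87 for L1 and 1.38 for IAP. With each KO against the other line's WT, differences of log2 ratios were, for the Miwi2 minus the Dnmt3L ratio 3.56 for L1 and 4.13 for IAP. With the mean of both WT libraries, differences of log2 ratios were, for the Miwi2 minus the Dnmt3L ratio 2.94 for L1 and 3.16 for IAP.

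With no count minimum, the counts were transcripts higher 175 (16.5 dpc), 19 (Dnmt3L KO, 10 dpp), 246 (Miwi2 KO), transcripts lower 155 (16.5 dpc), 3460 (Dnmt3L KO, 10 dpp), 238 (Miwi2 KO), miRNAs higher 17 (16.5 dpc), 5 (Dnmt3L KO, 10 dpp), 1 (Miwi2 KO) and miRNAs lower 2 (16.5 dpc), 8 (Dnmt3L KO, 10 dpp), 4 (Miwi2 KO). More genes are tested there by construction. With a minimum of 2000 reads, and so fewer genes, the counts were transcripts higher 4 (Dnmt3L KO, 10 dpp), 67 (Miwi2 KO) and transcripts lower 0 (16.5 dpc), 114 (Dnmt3L KO, 10 dpp). With protein-coding transcripts only, the counts were transcripts higher 1 (Dnmt3L KO, 10 dpp), 21 (Miwi2 KO) and transcripts lower 0 (16.5 dpc). With tags of 1 transcript only, the counts were transcripts higher 0 (16.5 dpc), 2 (Dnmt3L KO, 10 dpp), 23 (Miwi2 KO) and transcripts lower 13 (Miwi2 KO). Vps35 reversed to a log2 ratio of -1.14 in the Miwi2 KO. With libraries thinned to the smallest, the counts were transcripts lower 0 (16.5 dpc) and miRNAs higher 1 (Dnmt3L KO, 10 dpp). With tags of 1 position only, KO minus WT differences in percentage points were 10 nt overlaps on other transcripts 0.298 (Dnmt3L KO, 10 dpp), 1.71 (Miwi2 KO). Both reversed. Without the 10 most abundant sequences, KO minus WT differences in percentage points were piRNA-size reads 2.97 (16.5 dpc), -10.3 (Dnmt3L KO, 10 dpp), -0.950 (Miwi2 KO).

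Depth limited the fixed lists, since miRNAs with under 1000 reads were not compared, and it limited the segments found in few genes. Pools without a second library limited every comparison.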

Other observations

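The base bias of L1 reads differed between the libraries. L1 sense reads had U at position 1 in 50.4% in the Miwi2 WT, 70.7% in the Miwi2 KO, 59.2% in the Dnmt3L WT and 78.4% in the Dnmt3L KO at 10 dpp, and in 74.8% and 76.0% in the Dnmt3L WT and KO at 16.5 dpc. L1 antisense reads had A at position 10 in 38.5% and 65.1% in the Miwi2 WT and KO, 32.6% and 58.5% in the Dnmt3L WT and KO at 10 dpp, and 66.4% and 63.2% at 16.5 dpc. These values were chosen after they were seen, and their differences were not tested. IAP antisense reads had U at position 1 in 76.8% and 85.1% in the Miwi2 WT and KO, 83.3% and 88.0% in the Dnmt3L WT and KO at 10 dpp, and 76.3% and 70.9% at 16.5 dpc. The sense share of IAP reads was 46.6% and 32.001% in the Miwi2 WT and KO, 37.3% and 35.8% in the Dnmt3L WT and KO at 10 dpp, and 45.5% and 52.6% at 16.5 dpc. The mean length of L1 sense reads was 26.1 nt in the Dnmt3L KO at 10 dpp and 26.9 to 27.7 nt in the other libraries.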
